A study of Arabidopsis thaliana with 16 samples.

How the data were processed

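Arabidopsis seedlings were profiled by RNA-seq and by bisulfite sequencing. Per the labels' protocols, RNA libraries were made with a stranded mRNA kit from whole seedlings. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and BSMAP and the genome build TAIR10, with no versions. Which of these tools served which assay is not given in the sources used here. The 4 deposited tables have the layout of a Cufflinks comparison table. Of these, 2 compare dd in white light and Col-0 under UV-B with Col-0 in white light, and 2 list raised transposons. Each comparison table held 69252 annotated entries, of which 34973 were transposons or transposon genes and 27652 protein-coding genes.

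The deposited expression values are FPKM, per the file headers and their range, with 1 pooled value per group. The authors' deposited p-values and q-values compare the groups. Every entry with q under 0.05 was marked significant in the tables, and 20416 entries in the dd table and 20595 in the UV-B table had been tested. The smallest p-value in the authors' deposited tables was shared by 74 and 413 entries, so small values are not ranked further. Both tables list the same Col-0 values up to a factor of 1.01, within 0.001 of that factor for 99.9% of 20304 entries above 1 FPKM. With no value per replicate, no test across replicates was run beyond the authors' own, and no replicate could be left out. Log2 fold changes were computed as the value in dd or under UV-B over that of Col-0 in white light, with no pseudocount. The deposited fold column has the inverse sign and was not used.

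Coordinates are locus ranges from the tables, written 1-based. A locus range can span several overlapping entries. Gene names came from the RefSeq table of the TAIR10.1 assembly, which matched 37840 of 69252 identifiers and 27442 of 27652 protein-coding genes, and from the gene lists. None of its coordinates were used. FPKM values of entries that overlap others, or share reads with near-identical copies, are uncertain, which holds for most transposon entries.

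Calls were counted at q 0.05 per direction. Before the data were examined, 20 gene lists with 279 members were fixed. They cover UV-B signalling, flavonoids, phenylpropanoids, DNA repair, RNA-directed DNA methylation, methylation maintenance, demethylation, silenced loci, heat, oxidative stress, salicylate, jasmonate, auxin and elongation, photosynthesis, the clock, senescence, roots, seed storage, dividing cells and epidermis. Calls in each list were compared with the other tested entries by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 80 tests, of which 8 passed. The median of each list was placed among 10000 random lists of the same size drawn from the same 20 expression bins. Both methods treat genes as independent, while members of a list can vary together. Their p-values and percentiles therefore do not measure the spread between replicates. Overlaps were compared with independent lists and with 1000 simulations of unchanged groups that share a control, whose share of the error variance was set to 0.5. The simulations called a set number of the most extreme entries, with no q threshold. The simulated covariance used errors derived from the authors' p-values. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

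Genes were named by a rule fixed before the data were examined. It takes DRM1, DRM2, UVR8, ROS1, SDC and FWA; the 2 members of each list with the largest change past q 0.05 and at least 1 FPKM in the higher group; and the 5 highest and 5 lowest changes among entries past q 0.05 with values above 0 in both groups and at least 5 FPKM in the higher one. In the transposon lists it takes the 5 entries with the highest value and the 5 shared entries with the highest summed value. It gave 19 genes for dd and 34 for UV-B. Other genes named were chosen after their values were seen.

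Depth was estimated from transposon entries over 1.2 kb long that overlap no other entry. The lowest nonzero products of value and length, above 0.01 and up to 1.7 times the smallest, were taken as 1 fragment in 1 of 2 pooled libraries. The estimates ranged from 12.6 to 17.1 M fragments for Col-0 in white light, 3.63 to 5.63 M for dd and 5.28 to 6.07 M for Col-0 under UV-B. They are rough, and no counts were derived from them. With the smaller libraries, low transcripts in dd and under UV-B are measured less precisely than in Col-0.

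The statistics were tested on simulated data with genes changed by known amounts. Errors were normal, of an assumed size set from expression by the same formula for both comparisons. The shares recovered therefore do not measure the power of the authors' test. For dd, 49% of 100 genes changed by 1 on the log2 scale and 97% of 100 changed by 2 were recovered among 20185 genes. For UV-B the shares were 48% and 97% among 20390 genes. Alternatives were a q threshold of 0.01, a log2 change of at least 1, a minimum of 1 FPKM, adjustment over all entries, centring on the median, pseudocounts of 1 and 0.1, leaving out entries at 0, other control shares and overlap by coordinates of at least 1 bp. Further ones were added after the data were seen. A first test of library size in the transposon analysis, the share higher among entries the authors tested, was replaced after its value was seen; both values are given. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.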

Results

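The study asked how ultraviolet B (UV-B) light affects DNA methylation and gene expression in Arabidopsis thaliana. Whole seedlings were grown on agar medium and frozen on day 10. Light was 60 mE of white light, with or without 1.5 mE of UV-B at 315 nm. The 16 samples comprise 8 RNA-seq libraries and 8 bisulfite sequencing libraries. RNA-seq covered Col-0, the wild type, and dd, a line of the same ecotype with T-DNA insertions in DRM1 and DRM2. DRM2 is the main enzyme that adds methyl groups to cytosines at the end of the RNA-directed DNA methylation pathway, and DRM1 is its close relative. Each RNA-seq group had 2 replicates, described by the labels as biological. The values analysed here cover dd in white light, Col-0 under UV-B and Col-0 in white light. The UV-B-treated dd libraries and the bisulfite libraries of Col-0, uvr8-6 and UVR8-FLAG plants were not analysed here. Values were fragments scaled by transcript length and library size (FPKM), 1 pooled value per group, so no spread between replicates can be given. The authors' q-values are the only test across replicates. Read totals are not part of these values. From the lowest values of isolated transposon entries, depth of the Col-0 white-light libraries was estimated at 3.69 times that of dd and 2.55 times that of Col-0 under UV-B.

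The first comparison asked which transcripts differ between dd and Col-0 in white light. DRM2 (AT5G14620, chromosome 5, 4715105 to 4718704) fell in dd, with 1.82 FPKM against 7.09 in Col-0 in the authors' deposited table (q = 0.0138). DRM1 (AT5G15380, chromosome 5, 4991347 to 4994924) was listed at 0.319 FPKM in dd and 0 in Col-0 and was not tested in the authors' deposited table. ROS1 (AT2G36490, chromosome 2, 15307907 to 15314807), the DNA glycosylase that removes methylated cytosines, fell from 7.02 to 0.907 FPKM in the authors' deposited table, a log2 change of -2.95 (q = 0.0138). SDC (AT2G17690, chromosome 2, 7682162 to 7685202), an F-box gene silenced by DNA methylation, had 8.59 FPKM in dd and 0.102 in Col-0, but did not pass the test in the authors' deposited table (the authors' p = 0.236). Salicylate defence genes were among those that rose, with PR2 and PAD3 past the threshold.

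In the authors' deposited table, 86 of 20416 tested entries passed q 0.05, 54 higher and 32 lower in dd. Protein-coding genes made up 72 of these entries, 42 higher and 30 lower. Among entries past q 0.05, above 0 in both groups and with at least 5 FPKM in the higher one, the largest rises were in AT4G07995 and AT3G00580. AT4G07995 went from 1.08 to 59.5 FPKM and AT3G00580, a transcribed region of unknown function, from 1.92 to 85.4 FPKM in the authors' deposited table. AT5G24240 (log2 change 4.27), the non-coding RNA AT4G04223 (3.24) and AT3G32030 (2.31) followed, computed from the authors' deposited table. Their Col-0 values were low, and a pseudocount of 1 reduced these changes to 2.64, 2.17 and 1.67. Within the same limits, the largest falls were in ENODL17, ROS1, AT5G35940, AT3G46700 and the cytochrome P450 gene CYP702A5. ENODL17 (AT5G15350, chromosome 5, 4984919 to 4986377), an early nodulin-like gene, fell from 160.4 to 4.27 FPKM in the authors' deposited table. Its locus starts 6428 bp before that of DRM1. Of the genes around it, SPX4 and DND1 had log2 changes of -0.04 and -0.11 and did not pass the test, while AT5G15340 (0.147 FPKM in dd and 0.466 in Col-0) and AT5G15360 (listed at 0 and 0.482) were not tested in the authors' deposited table. A local change of the DNA near the insertion stays open, as expression values alone cannot test it. AT5G35940 and AT3G46700 fell by 2.28 on the log2 scale and CYP702A5 fell by 2.11, computed from the authors' deposited table. UVR8, the UV-B photoreceptor, had 41.7 FPKM in dd and 42.9 in Col-0 and did not pass the test in the authors' deposited table. FWA, a homeobox gene silenced by DNA methylation, was near 0 in both groups and was not tested in the authors' deposited table.

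Among 16 salicylate defence genes tested, 2 were higher and none lower in the authors' deposited table, or 6 higher when adjusted over the list alone. PR2, a beta-1,3-glucanase, rose from 81.9 to 170.04 FPKM and PAD3, a camalexin biosynthesis gene, from 10.3 to 19.9 FPKM in the authors' deposited table. Calls of this list were more frequent than among other tested genes (Fisher's exact test, two-sided, adjusted p = 0.00805). This test and the random lists treat genes as independent, so 1 difference between the pooled groups could move many members together. With a 2-fold change also required, the list lost that call (Fisher's exact test, adjusted p = 0.241; range 0.00805 to 1 over the alternatives). Of 16 members, 15 had the higher value in dd, and the list's median log2 change of 0.41 was above all of 10000 random lists matched on expression. Of 13 jasmonate genes tested, 1 rose and none fell in the authors' deposited table, or 3 rose and 1 fell adjusted over the list alone. By value 11 were higher and 2 lower, with a median log2 change of 0.25 at percentile 100 of matched random lists. The riser was VSP2, a vegetative storage protein, from 64.2 to 101.4 FPKM in the authors' deposited table. SAG13, a senescence-associated gene, was the single member of 5 tested senescence genes that passed, rising from 24.2 to 43.3 FPKM in the authors' deposited table.

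Of 23 tested genes of RNA-directed DNA methylation, DRM2 alone passed the threshold in the authors' deposited table, also when adjusted over the list alone. Of 7 tested DNA demethylation genes, ROS1 alone passed in the authors' deposited table, with the other 6 at slightly higher values in dd. None of 17 tested genes of methylation maintenance and heterochromatin passed in the authors' deposited table, and none had an unadjusted p under 0.05. In total, 14 lists with tested members had no member past the threshold in the authors' deposited table. They cover UV-B signalling, flavonoids, phenylpropanoids, DNA repair, methylation maintenance, known silenced loci, heat shock, oxidative stress, auxin and elongation, photosynthesis, the circadian clock, roots, dividing cells and epidermis. By the authors' unadjusted p under 0.05 these lists held 2 root markers and 1 gene each of UV-B signalling, known silenced loci and oxidative stress. Adjusted over the list alone, 1 UV-B signalling gene was higher and 1 known silenced locus, QQS, was lower. Root markers had lower values in dd for 8 of 9 tested genes (median log2 change -0.30, below all 10000 matched random lists). Markers of dividing cells had a median of -0.28, at percentile 0.25 of such lists. No seed storage gene was tested.

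The second comparison asked which transcripts differ between Col-0 grown with UV-B and Col-0 in white light. Genes of flavonoid and anthocyanin synthesis rose together, 14 of 20 tested and none lower in the authors' deposited table. TT4, the chalcone synthase that starts the pathway, rose from 246 to 941 FPKM, and FLS1, a flavonol synthase, from 73.7 to 281 FPKM in the authors' deposited table. ELIP1 and ELIP2, early light-induced proteins of the chloroplast, rose from 21.3 to 103.1 and from 8.82 to 78.7 FPKM in the authors' deposited table. Fewer genes fell in 3 other groups, 4 of 13 tested jasmonate genes, 4 of 16 salicylate genes and 5 of 12 clock genes, and 1 gene rose in each, in the authors' deposited table. PIF4, a transcription factor that promotes elongation, fell from 42.8 to 16.6 FPKM in the authors' deposited table.

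In the authors' deposited table, 793 of 20595 tested entries passed q 0.05, 420 higher and 373 lower under UV-B, and 779 of them were protein-coding. By the rule for entries above 0 in both groups, the highest changes were in BAM5, ELIP2, AT5G62210, AT4G33720 and ELIP1. BAM5, a beta-amylase, rose from 4.21 to 54.1 FPKM and AT5G62210 from 14.1 to 83.03 FPKM in the authors' deposited table. AT4G33720 rose from 1.66 to 9.12 FPKM in the authors' deposited table. The lowest were ORA47, an AP2/ERF transcription factor, NATA1, an acetyltransferase, AIR1, AGP30 and MLP328. ORA47 fell from 5.61 to 0.935 FPKM, NATA1 from 19.8 to 3.64 FPKM and AIR1 from 61.8 to 14.1 FPKM in the authors' deposited table. AGP30, an arabinogalactan protein, fell by 2.09 and MLP328 fell by 2.00 on the log2 scale, computed from the authors' deposited table. All changes named as rises or falls in this comparison had q under 0.05 in the authors' deposited table, with q = 0.00249 as the smallest value it holds.

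Of 16 UV-B signalling genes tested, 7 rose and none fell in the authors' deposited table, or 9 and 1 when adjusted over the list alone. Besides both ELIP genes they were GPX7, CRY3, RUP2, HYH and SIG5. The bZIP factor HYH went from 94.6 to 162 FPKM and RUP2, a repressor of UVR8 signalling, from 15.8 to 29.1 FPKM in the authors' deposited table. HY5 had 37.5 FPKM under UV-B and 26.8 in white light and missed the threshold in the authors' deposited table (q = 0.103). UVR8 itself had 37.2 and 42.6 FPKM in the authors' deposited table (q = 0.805). The higher calls of this list exceeded those of other tested genes (Fisher's exact test, adjusted p = 5.45e-07). For flavonoid and anthocyanin genes the same test gave an adjusted p of 4.82e-18 (Fisher's exact test), and 19 members were higher adjusted over the list alone. Their median log2 change was 1.65. The list tests under UV-B also treat genes as independent, so small p-values do not measure the spread between replicates. Of 18 phenylpropanoid and sinapate genes, 5 rose and 1 fell in the authors' deposited table, also when adjusted over the list alone (Fisher's exact test for higher calls, adjusted p = 0.000474). The glucosyltransferase gene UGT84A1 rose from 3.94 to 12.1 FPKM and UGT84A2 from 30.2 to 64.8 FPKM in the authors' deposited table. PAL4, a phenylalanine ammonia-lyase, fell from 6.78 to 4.31 FPKM in the authors' deposited table.

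Of 12 oxidative stress genes, 4 rose in the authors' deposited table, or 5 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000988). CAT2, a catalase, rose from 401 to 847 FPKM and CSD1, a superoxide dismutase, from 103.9 to 204 FPKM in the authors' deposited table. Requiring a 2-fold change ended the call of this list (Fisher's exact test, adjusted p = 0.461; range 0.000241 to 0.461). Among 16 salicylate defence genes 4 fell and 1 rose in the authors' deposited table, or 6 and 2 adjusted over the list alone (Fisher's exact test for lower calls, adjusted p = 0.00185). PR2 fell from 81.2 to 34.3 FPKM and PR1 from 31.9 to 14.9 FPKM, while PR5 rose from 23.7 to 41.7 FPKM in the authors' deposited table. Among 13 jasmonate genes 4 fell and 1 rose in the authors' deposited table, or 6 and 1 adjusted over the list alone (Fisher's exact test for lower calls, adjusted p = 0.000988). VSP1 fell from 34.1 to 12.5 FPKM, MYC2, the central transcription factor of the response, from 19.3 to 11.3 FPKM, and the defensin gene PDF1.2 rose from 25.4 to 41.3 FPKM in the authors' deposited table. A required 2-fold change ended both calls (Fisher's exact test, adjusted p = 0.0633 for salicylate, range 0.00189 to 0.0633, and 0.543 for jasmonate, range 0.00101 to 0.543).

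Of 12 clock genes 5 fell and 1 rose in the authors' deposited table, or 5 and 2 adjusted over the list alone (Fisher's exact test for lower calls, adjusted p = 3.61e-05). Those that fell were PRR5, PRR7, PRR9, LUX and GI, while LHY, which peaks at dawn, rose. PRR9 fell from 2.44 to 0.779 FPKM in the authors' deposited table, and PRR7 fell by 1.35 on the log2 scale. Of 13 auxin and elongation genes, EXPA8, an expansin, and PIF4 fell in the authors' deposited table, or 6 genes adjusted over the list alone. EXPA8 went from 82.4 to 30.5 FPKM in the authors' deposited table, and 12 of 13 values in this list were lower under UV-B. Its lower calls missed the threshold against other genes (Fisher's exact test, adjusted p = 0.163). Of 19 photosynthesis genes, LHCB1.2 fell from 5314 to 3340 FPKM and RBCS2B rose from 2797 to 3946 FPKM in the authors' deposited table. Adjusted over the list alone, 2 were higher and 1 lower. By value 14 of 19 were lower and 5 higher, and the median log2 change of -0.14 lay at percentile 0 of matched random lists. SAG13 fell from 23.99 to 13.4 FPKM and was the only one of 5 senescence genes to pass in the authors' deposited table. NRT2.1, a nitrate transporter, rose from 0.355 to 2.38 FPKM and was the only one of 10 root markers to pass in the authors' deposited table. Adjusted over the list alone, senescence and root markers each had 1 higher and 1 lower gene.

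No gene passed the threshold in the authors' deposited table in 8 lists with tested members. These were DNA repair, RNA-directed DNA methylation, methylation maintenance, DNA demethylation, known silenced loci, heat shock, dividing cells and epidermis. The authors' unadjusted p was under 0.05 for 2 of 18 DNA repair genes and 1 of 17 methylation maintenance genes, and for none of the others. The 2 repair genes were the photolyase gene UVR3 (log2 change 0.74) and the damage-binding gene DDB2 (0.44), computed from the authors' deposited table. Adjusted over the list alone, 1 repair gene was higher. By value 14 of 18 repair genes were higher and 4 lower, with a median log2 change of 0.15 at percentile 98.8 of matched random lists. DRM2 had 6.74 and 7.03 FPKM and ROS1 6.43 and 6.96 FPKM in the authors' deposited table, both without passing the test. DRM1 was listed at 0 in both groups, and SDC (0.110 and 0.101 FPKM) and FWA (listed at 0 under UV-B) were not tested in the authors' deposited table.

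**Figure D1:**
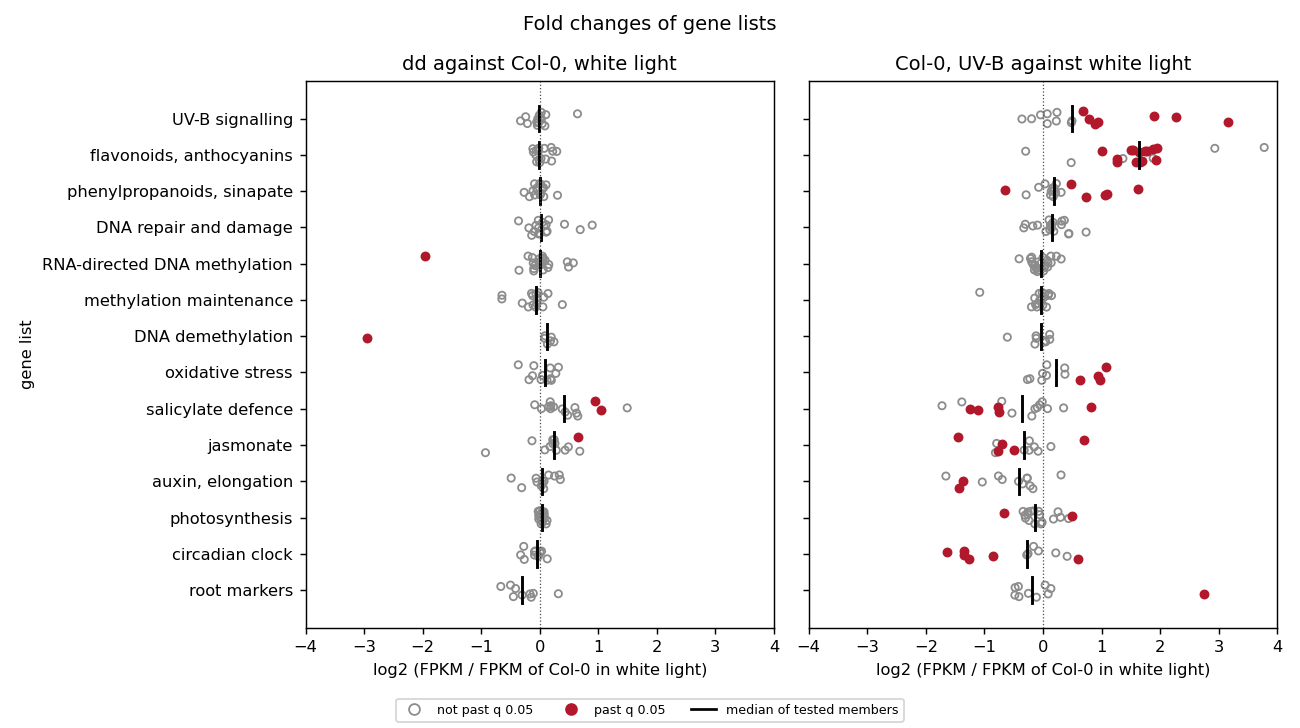
Log2 fold changes of tested genes in 14 gene lists (x axis, FPKM over FPKM of Col-0 in white light; y axis, list), with dd on the left and UV-B on the right. Each point is a gene, filled where it passed q 0.05 in the authors' deposited table, and bars are list medians; flavonoid genes had a median of 1.65 under UV-B and -0.01 in dd.

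A further analysis asked which entries changed in both comparisons. Of 30 shared entries, 20 changed in opposite directions and 10 in the same direction in the authors' deposited table. Phosphate starvation genes such as SPX1, IPS1, PS2, PEPC1, PAP14 and MGDC were lower in dd and higher under UV-B; they were named after their values were seen. IPS1, a non-coding RNA induced by low phosphate, had 44.7 FPKM in dd, 97.8 in untreated Col-0 and 212 under UV-B in the authors' deposited table. PR2, VSP2 and SAG13 went the other way, with PR2 at 170.04 FPKM in dd and 34.3 FPKM under UV-B in the authors' deposited table. Genes lower in both included the thalianol synthase gene THAS1 and CYP708A2 and CYP705A5 of the same gene cluster.

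Among 20135 entries tested in both tables, 12 were higher in dd and lower under UV-B, against 0.760 for independent lists (Fisher's exact test, adjusted p = 2.67e-11). The reverse held for 8 entries against 0.661 (Fisher's exact test, adjusted p = 4.23e-07). Lower in both were 7 entries against 0.593 (Fisher's exact test, adjusted p = 2.13e-06). Higher in both were 3 entries against 0.847 (Fisher's exact test, adjusted p = 0.0524), AT5G35480, MRU1 and the transposon gene AT2G04460. These tests treat entries as independent, which they are not. Several are phosphate starvation genes or members of the THAS1 cluster, and AT5G35480 and MRU1 are neighbours. Both comparisons used the same Col-0 libraries, so shared error alone gives overlap. The simulations drew error alone and applied no q threshold. They called the most extreme entries in the observed numbers, 41 higher and 32 lower in dd, 416 and 373 under UV-B. Where observed calls reflect real changes, the simulated same-direction overlap is too large. Simulated unchanged groups with a control share of 0.5 gave 21.7 entries in the same direction (95% range 14 to 29) and a mean of 0.001 in opposite directions. With shares of 0.25 and 0.75 the same-direction mean was 7.04 (3 to 12) and 49.7 (42 to 58), and the opposite-direction mean was at most 0.103. Across 19171 expressed genes, which are not independent replicates, the log2 changes correlated at Pearson's r = 0.20 (Spearman's rho = 0.20). The simulated correlations of 0.25, 0.50 and 0.75 equal the 3 shares put in by construction, so they are no test of this value. The covariance was 0.0208, above the simulated 0.0126 at 0.25 and below 0.0252 at 0.5 and 0.0378 at 0.75. The controls could not be split, so how much of the same-direction overlap comes from them is not known, and all of it may.

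**Figure D2:**
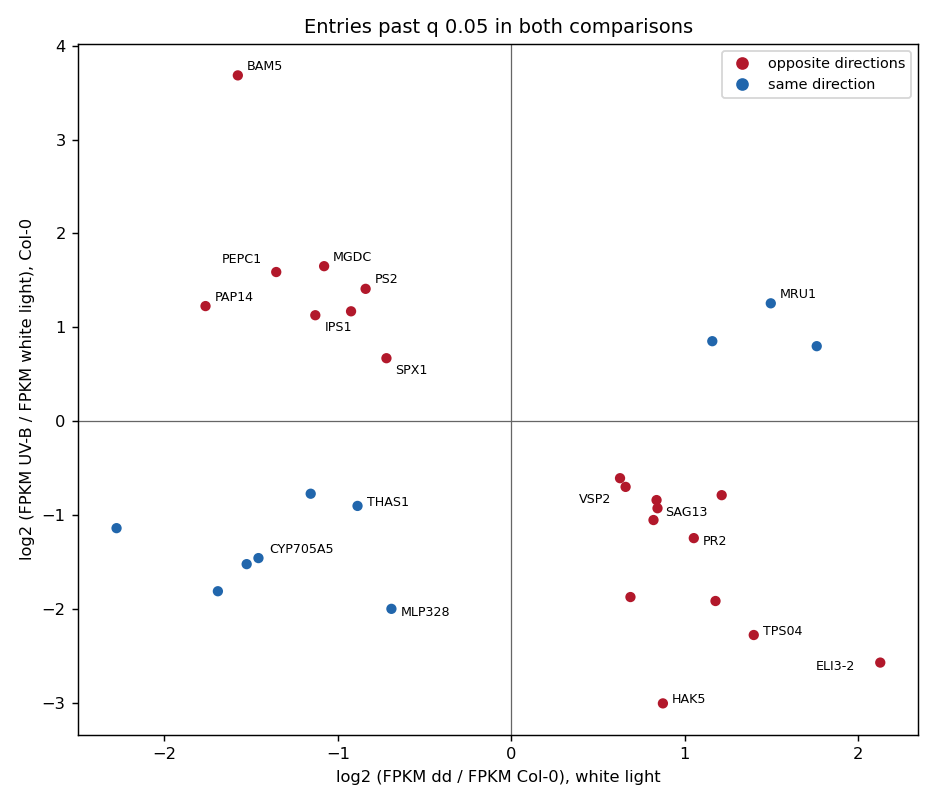
Log2 fold change in dd (x axis) against that under UV-B (y axis), both over Col-0 in white light, for 30 entries past q 0.05 in both of the authors' deposited tables. Each point is an entry, red for the 20 that changed in opposite directions and blue for the 10 that changed the same way.

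The last comparison concerned transposons, which DNA methylation keeps silent. Transposon entries past q 0.05 numbered 7 higher and none lower in dd, and 3 higher and 1 lower under UV-B in the authors' deposited table. In dd, AT1TE58825 (chromosome 1, 17713520 to 17714780) had 11.7 FPKM and AT5G35207 (chromosome 5, 13471681 to 13472500) 5.55 FPKM in the authors' deposited table, both listed at 0 in Col-0. AT2TE22550, AT5TE25535 and AT3TE76405 were also listed at 0 in Col-0, and AT5G35935 rose from 0.124 to 3.14 FPKM in the authors' deposited table. AT2G04460 (chromosome 2, 1547328 to 1553647) rose in both comparisons, with 9.56 FPKM in Col-0 and 21.4 in dd, and 17.1 under UV-B, in the authors' deposited tables. AT3G43955 rose from 1.28 to 3.66 FPKM and AT3TE43615 from 9.37 to 19.4 FPKM under UV-B, where AT1G35612 fell from 23.7 to 12.7 FPKM in the authors' deposited table.

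Transposon entries were 7 of 54 higher calls in dd and 450 of 20416 tested entries (Fisher's exact test, adjusted p = 0.000699). Of these 7, only AT2G04460 and AT5G35935 were above 0 in Col-0, and only AT1TE58825 and AT2TE22550 overlap no other entry. Leaving out entries at 0 left 45 higher calls in dd, and the test was not repeated on them. Under UV-B transposon entries were 3 of 420 higher calls and 1 of 373 lower calls, against 445 of 20595 tested entries. These shares, 0.71% and 0.27%, were below the 2.16% of tested entries, the opposite direction to dd. The adjusted p was 0.0525 for higher and 0.0116 for lower calls (Fisher's exact test). The authors also listed raised transposons, 270 entries in dd and 269 under UV-B. These lists held all 270 transposon entries of the dd table, and 269 of 270 of the UV-B table, that were above 0 in both groups and at least 1.5-fold higher. The lists were chosen on these libraries, so their direction is not independent evidence. Of their entries, 2 in dd and 3 under UV-B passed q 0.05 in the authors' deposited tables, and 160 and 163 were not tested. Lower by at least 1.5-fold were 143 entries in dd and 142 under UV-B, so the share higher was 65.4% (exact 95% interval 60.6 to 70.0) and 65.5% (60.7 to 70.1). Counting entries listed at 0 in 1 group turned the shares to 33.8% and 33.9%. Scaling to the mean of the 4 ratios that recur most often among untested entries gave 16.2% and 11.9%.

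The highest values in the dd list belonged to AT5TE92730, AT3TE45330, AT1TE80805, AT3TE62825 and AT5TE32535. AT3TE45330 (chromosome 3, 10900843 to 10904458) had 756 FPKM in dd and 9.28 in Col-0, and AT5TE92730 had 802 and 519.98 FPKM in the authors' deposited table. Under UV-B the highest were AT5TE30190, AT1TE65155, AT3TE22600, AT2TE80000 and AT3TE34080. AT5TE30190 (chromosome 5, 8348160 to 8355925) had 2155 FPKM under UV-B and 1407 in white light in the authors' deposited table. AT1TE65155 and AT3TE22600, on different chromosomes, had the identical value of 551 FPKM under UV-B in the authors' deposited table. None of these 10 entries passed q 0.05 in the authors' deposited tables. All but AT3TE22600, whose locus spans 63 bp, overlap other entries, so their values may come from other features. AT1TE80805 has the locus range of the protein-coding gene AT1G66090, itself higher in dd (24.1 FPKM against 15.1 in Col-0). Of the listed entries, 231 of 270 in dd and 231 of 269 under UV-B overlap others. The lists shared 96 entries, against 47.7 for independent lists among 504 entries above 0 in all groups (Fisher's exact test, p = 5.95e-23). Unchanged groups gave 63.4 shared entries with a control share of 0.25 (95% range 54 to 73), 81.6 with 0.5 (72 to 91) and 104 with 0.75 (95 to 113). The reading of 96 depends on this share, which is not known. The simulation also left out the smaller dd and UV-B libraries, which can place the same low entries in both lists. At the recurring ratios lay 51 of 270 listed entries in dd and 66 of 269 under UV-B. The highest summed values among shared entries were those of AT3TE34080, AT1TE30380, AT5TE28480, AT5TE32535 and AT2TE27080, all of which overlap other entries. AT3TE34080 had 129 FPKM in dd, 346 FPKM under UV-B and 23.6 in Col-0 in the authors' deposited table of dd.

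**Figure D3:**
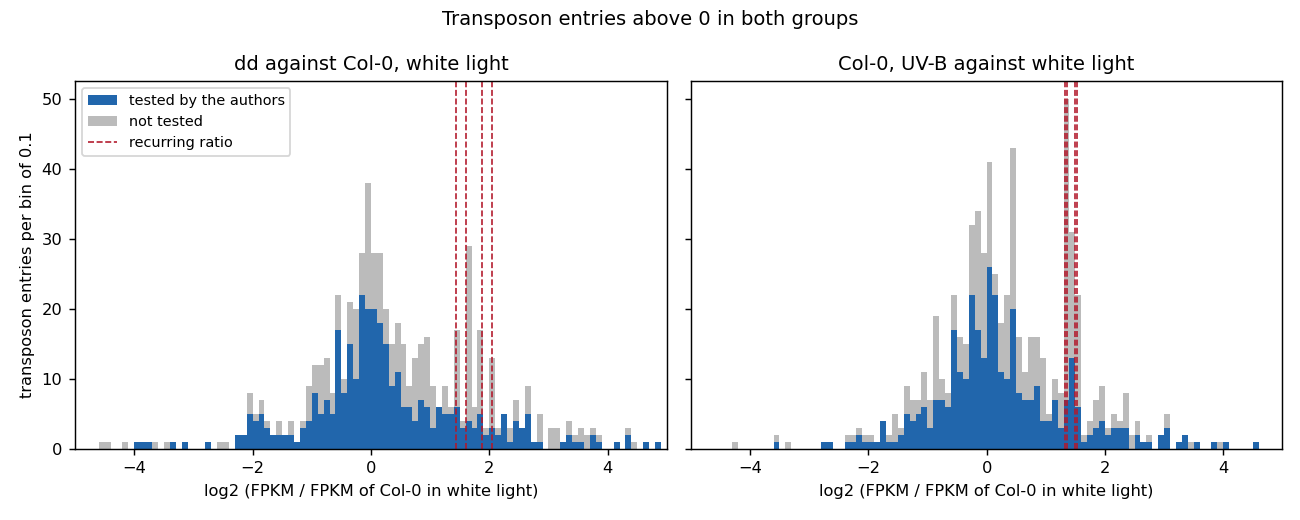
Log2 ratio to Col-0 in white light (x axis) of transposon entries above 0 in both groups (y axis, entries per bin of 0.1), with 58 entries in dd and 46 under UV-B outside the axis. Blue entries were tested by the authors and grey ones were not; dashed lines mark the 4 ratios that recur most often among untested entries, from 1.44 to 2.05 in dd and from 1.33 to 1.53 under UV-B.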

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

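The alternatives of the transposon shares and the counts of protein-coding genes alone were added only after the result was seen. No paired analysis was possible because the tables hold 1 pooled value per group, and for the same reason no replicate could be left out. A q threshold of 0.01 left 0 entries in dd (757 had an unadjusted p under 0.05 in the authors' test) and 519 under UV-B, since the smallest q in the dd table is 0.0138. It left 0 shared entries, 0 transposon entries among the higher calls in dd, and 0 (dd) and 2 (UV-B) entries of the raised-transposon lists, with 0 shared. A log2 change of at least 1 left 56 entries in dd, 246 under UV-B, 14 shared between the comparisons and 4 of 8 list calls. With a pseudocount of 1 as well, 51 and 192 remained by number. Higher transposon entries past q 0.05, in place of the lists, were 7 in dd, 3 under UV-B and 1 in both. Requiring 1 FPKM left 124 and 112 list entries, 42 of them shared. The share higher among transposon entries changed at least 1.5-fold reversed under 2 settings. It was 33.8% in dd and 33.9% under UV-B with entries at 0 in 1 group counted, and 16.2% and 11.9% when scaled to the one-fragment ratio. The second follows from construction, since the scaling lowers every ratio. The first arose because 1210 and 1161 entries were above 0 in Col-0 alone, against 421 in dd alone and 398 under UV-B alone. Among entries overlapping no other, entries the authors tested and entries away from the one-fragment ratios, the share stayed above 50%, from 59.0% to 81.2%. Median centring and pseudocounts of 1 and 0.1 changed no direction in 150 recomputed named-gene values, but they could not have done so. A pseudocount added to both groups cannot reverse a direction. Centring shifted values by only 0.0035 in dd and 0.0025 under UV-B, less than any named change. Of 24 list calls recomputed under other thresholds, 19 held. By the rough depth estimates, low transcripts are limited more in dd and under UV-B than in Col-0 in white light. The estimated ranges of dd and UV-B overlap.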

Other observations

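The gene groups of this part and the tests on them, and those on lone and called transposon entries, were chosen only after the result was seen, and the matched test of library size was chosen after a first test of it had been seen. Phosphate starvation genes moved apart in the 2 comparisons. Of 19 tested, 6 fell and none rose in dd, and 12 rose and none fell under UV-B in the authors' deposited tables, or 12 and 17 adjusted over the list alone, while all 19 values were lower in dd and all 19 higher under UV-B. The phosphatase gene PEPC1 had 9.67 FPKM in dd, 24.7 in untreated Col-0 and 73.8 under UV-B, and MGDC, which makes galactolipids when phosphate is low, 6.81, 14.4 and 44.8 FPKM in the authors' deposited tables. Median log2 changes were -0.55 and 0.70. Of 6 triterpene cluster genes, 4 fell in each comparison in the authors' deposited tables, or 5 in each adjusted over the list alone. Both comparisons share their Col-0 libraries, so the second fall is no independent support for the first. Unchanged groups gave 7.04 to 49.7 same-direction entries in simulations that called the observed numbers of entries. The median log2 change of the triterpene genes in dd was -1.31, further down than the root markers' -0.30 (95% bootstrap interval -0.50 to -0.11). No interval of this difference was computed, so a smaller share of roots in dd stays open for these genes. CYP705A5 went from 22.1 FPKM in Col-0 to 8.05 in dd and 7.98 under UV-B in the authors' deposited tables. Of 6 SAUR19 subfamily genes, which promote cell expansion, SAUR20 and SAUR21 fell under UV-B in the authors' deposited table and all 6 values were lower (median log2 change -1.64), with 5 past the threshold adjusted over the list alone. In dd none passed, and 0 had an unadjusted p under 0.05.

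The phosphate pattern was set against 4 explanations, using the 13 members not called in both comparisons where possible. Error of the shared Col-0 libraries would move both comparisons the same way, but 100% of the 13 members moved in opposite directions (exact 95% interval 75.3 to 100). A larger share of roots under UV-B is argued against by root markers, whose median log2 change was -0.18 (95% bootstrap interval -0.44 to 0.09). A smaller share of roots in dd remains open: root markers there had a median of -0.30 (-0.50 to -0.11), and although the median of all 19 phosphate genes, -0.55, lay below that interval and so met the bound set against this explanation, the difference of the medians, computed only afterwards, was -0.25 (95% bootstrap interval -0.67 to 0.05). An altered phosphate status of the plants stays open without independent support, as the genes were picked for this pattern; the 13 members had medians of -0.40 in dd and 0.56 under UV-B, at percentiles 0 and 100 of matched random lists, though supply on the plates and the response to genotype or light cannot be separated with pooled groups.

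The excess of higher transposon entries in dd (65.4%) may come in part from smaller dd libraries. Other entries matched on summed value times locus length were higher in 60.6%, a difference of 4.82 percentage points (95% bootstrap interval -0.67 to 9.88). This interval includes 0 but also allows a difference of several points, and the locus length used for matching is shared among overlapping entries. Reads of overlapping features stay open: 81.2% of 48 changed entries that overlap no other were higher (exact interval 67.4 to 91.1), but 16 of them lay at a one-fragment ratio, and of 18 that the authors tested 61.1% were higher (35.7 to 82.7). Release of silencing was not tested independently, since the 7 of 7 higher entries past the authors' threshold (exact binomial p = 0.0156) were known before this test and add no support.

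Under UV-B, the matched test went against smaller libraries as the whole cause of the excess. Matched other entries were higher in 56.7%, 8.87 percentage points less (95% bootstrap interval 3.46 to 14.1). Without entries at a one-fragment ratio the transposon share was 59.0% (exact interval 53.6 to 64.2), and among tested entries 60.5% (52.8 to 67.7). Both intervals include 56.7%, a value for matched entries not restricted in these ways, so smaller libraries stay open. The matched entries can themselves respond to UV-B. The share reversed to 33.9% when entries at 0 in 1 group were counted, as 1161 entries were above 0 in Col-0 alone and 398 under UV-B alone. Smaller UV-B libraries would leave more entries at 0, so these counts also leave that explanation open. Overlapping features stay open here too. Of 47 lone entries 80.9% were higher (exact interval 66.7 to 90.9), and 22 of the 47 lay at a one-fragment ratio. Higher were 64% of the 25 without those (42.5 to 82.0) and 66.7% of 18 tested ones (41.0 to 86.7). Whether silencing was released cannot be told from 4 entries past the authors' threshold, 3 of them higher (exact binomial p = 0.625).

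The matched test replaced another test of library size, whose bound, set before its value was known, took a share above 50% among transposon entries the authors tested as evidence against smaller libraries. The shares were 60.1% of 183 in dd (exact interval 52.6 to 67.3) and 60.5% of 177 under UV-B (52.8 to 67.7), against the explanation in both comparisons, and the replacement reversed this verdict for dd alone. The bound is doubted because other entries matched on value and length were also higher in more than 50%, without being transposons. Their shares were 60.6% in dd and 56.7% under UV-B. They were matched to all changed transposon entries, not to the tested ones alone. The bound is thus not shown to be wrong for tested entries. A reader who keeps the first bound would exclude smaller libraries as the whole cause in both comparisons. The lone-entry test was first read as evidence against overlapping features, before the one-fragment entries among them were counted. Tests of shared control error on the 96 shared transposon entries and on the 30 entries called in both comparisons were also run first and then dropped. The 96 lay above the simulated ranges at control shares of 0.25 and 0.5 (54 to 73 and 72 to 91) and inside that at 0.75 (95 to 113). The answer thus depends on the share, and library size was not modelled. Of the 30, 66.7% moved in opposite directions (exact interval 47.2 to 82.7), which left the bound of 50% open, but shared error gave at most 0.103 such entries on average in simulations, against 20 observed.

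For each comparison the 4 most frequent ratios among untested transposon entries were taken, a number fixed by choice. Within each set, the same 2 steps separated the ratios. In dd the steps were 0.167 and 0.449 on the log2 scale, and under UV-B 0.037 and 0.167. The ratios equal 2.70- to 4.14-fold in dd and 2.51- to 2.89-fold under UV-B, and 51 of 270 and 66 of 269 listed entries lay within 0.0015 of one of them.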
